A study of Cuscuta campestris with 9 samples.

How the data were processed

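Short RNAs were sequenced at full length from haustoria of the parasitic plant Cuscuta campestris (dodder) that had formed without a host. Per the labels' protocols, cut shoot tips were exposed to far-red light and pressed against agar until haustoria, the organs through which the parasite enters its host, were visible, and total RNA was taken from the dissected regions. There were 3 RNA samples. Each was divided over 3 treatments: decapping enzyme (Dcp), the pyrophosphohydrolase RppH, and no enzyme. This gave 9 libraries, 3 per treatment. The ligation used to build the libraries needs a 5′ monophosphate, so an RNA that ends in a cap or a triphosphate enters a library only after an enzyme has trimmed its end. The labels do not say whether the 3 RNA samples came from separate batches of plants, and p-values measure only the spread between these libraries.

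The deposited table holds raw counts of full-length transcripts per genomic interval and library, with no normalization, per the file header and the values, which were whole numbers. It also holds TPM values by the authors, per the file header. Within each library the TPM equalled the deposited count divided by 1 constant (largest relative deviation 3.1e-15), so the TPM was not scaled by length. The total recovered from this constant was taken as the library total, but what it counts is not stated in the sources used here. The submitters' processing notes name cutadapt, Bowtie2, SAMtools and bedtools without versions. How reads that map to several copies were assigned is not given in the sources used here, and values of near-identical copies, such as those of U1 or of tRNA genes, are therefore uncertain for each copy. Scaffold names carry the prefix of the assembly Ccam0.32, and coordinates are given on those scaffolds, counted from 1. The gene table supplied as a reference belongs to another assembly and was not used here.

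The table lists 2535 intervals in 3 categories: 94 intervals of spliceosomal snRNA, 2315 of pre-tRNA from 496 tRNA genes, and 126 microRNA primary transcripts that the table describes as induced at the host interface. The snRNA category is labelled as capped in the table itself, so this class was marked as capped before the comparisons made here. All 66 intervals with 0 counts in every library were snRNA. Each listed pre-tRNA or microRNA interval had at least 1 count, so those lists hold only what was seen. Of 13 RNA classes fixed before the data were examined, 3 had members in the table: microRNA loci (126 intervals), U1, U2, U4 and U5 snRNA (94) and tRNA (2315). The lists of U6, U3, 7SL, RNase MRP and P RNA, 5S rRNA, large rRNA, other snoRNA, messenger RNA, organellar RNA and other small RNA loci matched 0 intervals each.

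Library totals so recovered ran from 24974484 to 46034864, and the listed intervals held 630 to 34529 counts. A single count was worth 0.0217 to 0.04 TPM. Counts are not known to be independent molecules, since no molecular identifiers are mentioned, so intervals and floors cover counting error only. A fold against a group with 0 counts was taken against a floor of 3 counts over the group and is a lower bound.

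The design had assumed TPM values and limma. Because the table held counts, edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) was used, as the design provided for. Each SE given with an edgeR log2 value was back-calculated, as its absolute value divided by the square root of the test's F statistic. It is not a standard error that edgeR itself estimates. Offsets were the recovered library totals with no further normalization factor, all 9 libraries shared 1 estimate of the spread, and tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The tested intervals were the 34 with a TPM of at least 1 in at least 3 libraries: 9 microRNA, 8 snRNA and 17 pre-tRNA intervals from 9 tRNA genes. After the data were seen, a second level was added, in which pre-tRNA intervals were summed per tRNA gene and the 354 of 716 loci with at least 10 counts over all libraries were tested (69 microRNA loci, 18 snRNA loci and 267 tRNA genes). Class totals were compared by exact permutation tests, whose smallest two-sided p with 3 against 3 libraries is 0.1. Neither these tests nor the main edgeR fits use the pairing by RNA sample. The labels state no statistical model, so the RNA sample as a block was an alternative fit. An exact test of 3 pairs could not go below 0.25. Classes were tested with camera at a preset correlation of 0.01. Named features were, per contrast, up to 10 with the largest change in each direction among those past the threshold, changed alike in all 3 RNA samples and with a mean TPM of at least 10, then the 3 with the highest mean TPM per class and per snRNA type, then the 10 highest overall. Others are said to have been chosen after their values were seen.

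Libraries with the same number came from the same RNA sample per the labels, so the numbers pair the libraries. As a check, deviations from the group means had a mean correlation of 0.16 between libraries of the same number (9 pairs, −0.267 to 0.482). Between other libraries it was −0.0832 (18 pairs, −0.562 to 0.464). The ranges overlap, so the check does not decide the pairing, which rests on the labels. Counts of replicates of one treatment differed by more than sampling noise in all 9 pairs (chi-square divided by its degrees of freedom 3.65 to 8.07), so no library was a copy of another.

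Alternatives were the RNA sample as a block, limma 3.58.1 with pseudocounts of 0.1, 1 and 10 or with a trend, DESeq2 1.42.0, other filters and scalings, fits of 2 groups, and fits without each library or each RNA sample. Python 3.11.15 with SciPy 1.17.1 was used for ratios and permutations. On simulated data for RppH against untreated, with the real untreated rates, edgeR called 45% of features raised 4-fold, 88.8% of those raised 16-fold and 100% of those raised 64-fold among 34 intervals, and 3 of 340 unchanged ones. Among 354 loci it called 14.2%, 58.6% and 99.6%, and 3 of 885 unchanged ones.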

Results

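Full-length short RNAs were counted in 9 libraries from host-free haustoria of Cuscuta campestris, 3 each from untreated RNA, RNA treated with decapping enzyme (Dcp) and RNA treated with the pyrophosphohydrolase RppH. Library totals of replicates 1 to 3, as recovered from the TPM, were 41321715, 46034864 and 26426312 for untreated RNA, 25660226, 40828047 and 29011242 for Dcp, and 27459027, 24974484 and 33362911 for RppH. The listed intervals held 1011, 645 and 630 counts in untreated libraries, 13840, 18369 and 10843 after Dcp, and 20981, 13578 and 34529 after RppH. The comparisons asked which RNAs had 5′ ends that became ligatable with each enzyme. The protocol reads a gain after both enzymes as a probable cap and a gain after RppH alone as a probable triphosphate. Spliceosomal snRNAs, which RNA polymerase II transcribes and caps, and pre-tRNAs, which RNA polymerase III transcribes, stood beside the primary transcripts of microRNAs.

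Spliceosomal snRNAs were almost absent from untreated libraries and abundant after either enzyme. Their total was 0.652 ± 0.356 TPM in untreated RNA, 400 ± 63.7 TPM after Dcp and 453 ± 147 TPM after RppH (SD, n = 3 each). Pre-tRNAs totalled 19.0 ± 5.09 TPM untreated, 35.8 ± 8.83 TPM after Dcp and 235 ± 59.3 TPM after RppH (SD, n = 3 each). MicroRNA primary transcripts totalled 1.13 ± 0.496 TPM untreated, 18.8 ± 10.7 TPM after Dcp and 92.7 ± 42.1 TPM after RppH (SD, n = 3 each). The ratio of RppH to untreated means was 696 for snRNA, 12.4 for pre-tRNA and 82.3 for microRNA, and that of Dcp to untreated means was 613, 1.88 and 16.7. Each total was higher after each enzyme than in untreated RNA in all 3 RNA samples. The exact two-sided permutation p, which leaves out the pairing, was 0.1 in each case, the smallest that 3 against 3 libraries allow.

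**Figure D1:**
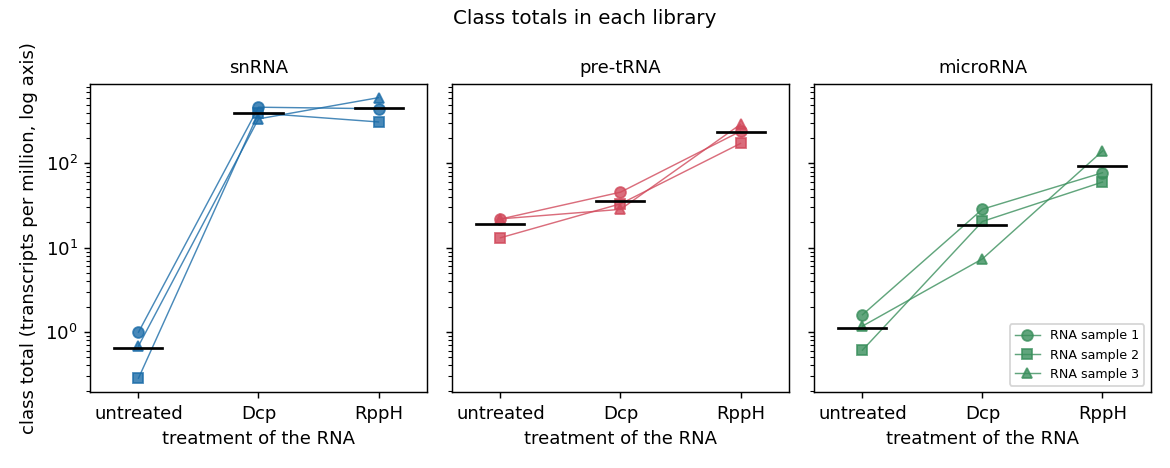
Class totals in TPM (log axis) in each library, by treatment, with 1 panel per RNA class; lines join libraries of the same RNA sample and black bars mark means of 3 libraries. The snRNA means after Dcp (400 TPM) and RppH (453 TPM) lie close together, whereas the pre-tRNA mean is 35.8 TPM after Dcp and 235 TPM after RppH.

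RppH raised nearly every tested interval. Of 34 intervals, 33 were higher than in untreated RNA and 0 were lower: all 9 microRNA, all 8 snRNA and 16 of 17 pre-tRNA intervals (edgeR quasi-likelihood, Benjamini-Hochberg; 0 were lower at an unadjusted p under 0.05 or with DESeq2). Adjusted over the list alone, the counts were again 9, 8 and 16. The interval left out was an 82-nt form of the alanine pre-tRNA on scaffold 16 (2759665 to 2759746, minus strand), with an adjusted p of 0.0529 in edgeR, which was 0.036 with the RNA sample as a block. Only forms of this alanine pre-tRNA had an untreated mean of at least 1 TPM. The other tested intervals passed the filter through their treated libraries, which largely sets the share that rose. Without a filter 220 of 2469 intervals were higher and 0 lower. The dominant U1 copy, the snRNA that pairs with 5′ splice sites, lay on scaffold 1 (2523679 to 2523838, plus strand) and went from 0.499 ± 0.227 TPM to 380 ± 127 TPM (SD, n = 3). Its log2 fold change was 9.58 (SE 0.614, edgeR adjusted p = 1.45e-12), with the same direction in 3 of 3 RNA samples. U2, which pairs with the branch site, had its most abundant copy on scaffold 79 (315044 to 315239, plus strand), at 0.0933 ± 0.13 TPM untreated and 23.8 ± 7.29 TPM after RppH (log2 fold change 7.90, SE 0.949, edgeR adjusted p = 1.03e-07). A U2 copy on scaffold 29 (734845 to 735040, plus strand) had 1 untreated count and reached 15.6 ± 2.11 TPM. The ratio of its pooled rates was 1755, with a 95% counting interval of 314 to 69353. Both tested U4 copies, on scaffold 12 (1865644 to 1865777, plus strand) and scaffold 99 (530255 to 530388, minus strand), had 0 untreated counts and were at least 78.2-fold and at least 60.1-fold higher after RppH.

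Among microRNA loci, ccm-MIR12463b (scaffold 7, 1050575 to 1050710, plus strand) rose from 0.217 ± 0.172 TPM to 15.4 ± 7.96 TPM after RppH (SD, n = 3; log2 fold change 6.11, SE 0.876, edgeR adjusted p = 7.62e-07). For ccm-IIM-27 (scaffold 29, 1788882 to 1789031, minus strand) the change was from 0.0757 ± 0.131 TPM to 12.1 ± 6.23 TPM, and for ccm-IIM-12a (scaffold 7, 1280002 to 1280148, plus strand) from 0.0523 ± 0.0544 TPM to 8.80 ± 3.31 TPM. Of 69 microRNA loci with at least 10 counts, 66 were higher after RppH. So were 18 of 18 snRNA loci and 239 of 267 tRNA genes, in all 323 of 354 loci. The minimum of 10 counts was taken over all libraries, so it too favoured loci with counts after an enzyme. With the RNA sample as a block, 203 of the 354 loci passed: 38 microRNA loci, 16 snRNA loci and 149 tRNA genes. Without RNA sample 1 there were 196, and without RNA sample 3 there were 211.

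All these changes are relative to the library total. Scalings that take the tested intervals as their reference moved RppH against untreated by 6.32 on the log2 scale (median of ratios) or by 3.20 (TMM). With the first, 7 intervals were called higher and 7 lower, and with the second 24 higher and 4 lower. Under median of ratios the 3 most abundant alanine pre-tRNA intervals and ccm-MIR12463b pointed the other way, while the dominant U1 copy (log2 fold change 3.30) and both U2 copies (1.71 and 4.52) stayed higher. Both U4 copies (adjusted p = 0.113 and 0.166), ccm-IIM-27 (log2 fold change 1.35, adjusted p = 0.188) and ccm-IIM-12a (0.79, adjusted p = 0.422) did not pass under it. Among the 354 loci, median of ratios gave 15 higher and 10 lower, and TMM gave 66 higher and 8 lower.

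Dcp raised snRNA and microRNA intervals and few pre-tRNAs. Compared with untreated RNA, 20 of 34 intervals were higher and 0 were lower: 9 of 9 microRNA, 8 of 8 snRNA and 3 of 17 pre-tRNA intervals, with the same counts when adjusted over the list alone (edgeR; 0 were lower at an unadjusted p under 0.05 or with DESeq2). The dominant U1 copy reached 329 ± 46.4 TPM (log2 fold change 9.37, SE 0.609, edgeR adjusted p = 1.98e-12, higher in 3 of 3 RNA samples). Other U1 copies on scaffold 29 (739741 to 739898, plus strand) and scaffold 1 (2337806 to 2337965, plus strand) reached 9.99 ± 4.21 TPM and 6.91 ± 0.743 TPM after Dcp, from 4 and 2 untreated counts. The U2 copies on scaffolds 79 and 29 reached 24.0 ± 6.48 TPM and 17.4 ± 3.97 TPM. The U4 copies were at least 52.8-fold and at least 60.4-fold higher. ccm-MIR12463b reached 3.44 ± 2.46 TPM (log2 fold change 3.95, SE 0.809, edgeR adjusted p = 0.000161), ccm-IIM-27 2.14 ± 1.33 TPM and ccm-IIM-12a 3.28 ± 2.25 TPM. With limma and a pseudocount of 10 these 3 loci did not pass (adjusted p = 0.42, 0.456 and 0.141) and 8 intervals were called, and under median of ratios ccm-MIR12463b (log2 fold change 0.50, adjusted p = 0.466) and ccm-IIM-27 (1.74, adjusted p = 0.0561) did not. Median of ratios scaling moved Dcp against untreated by 3.39 on the log2 scale and gave 10 intervals higher and 9 lower, and TMM moved it by 1.32 and gave 14 higher and 1 lower. The 3 pre-tRNA intervals that rose belonged to 2 genes, chosen here after their values were seen: asparagine tRNA3-AsnGTT on scaffold 90 (858740 to 858827 and 858740 to 858826, plus strand) and arginine tRNA1-ArgCCT on scaffold 126 (1387349 to 1387441, plus strand). The shorter asparagine form was higher in 2 of 3 RNA samples, and its adjusted p in edgeR was 0.011, or 0.0555 with the RNA sample as a block. Among loci with at least 10 counts, Dcp raised 19 of 69 microRNA loci, 16 of 18 snRNA loci and 13 of 267 tRNA genes, 48 in all. Adjusted over the list alone the counts were 24, 18 and 3. The total was 30 with the block, 6 without RNA sample 1 and 22 without RNA sample 2.

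The 3 most abundant pre-tRNA intervals came from a single alanine gene, tRNA14-AlaTGC on scaffold 16 (minus strand), and shared the 5′ end at 2759746. They were 86 to 88 nt long. The 87-nt form had 3.43 ± 1.44 TPM untreated, 4.94 ± 0.403 TPM after Dcp and 13.9 ± 4.98 TPM after RppH (SD, n = 3). Its rise after RppH passed (log2 fold change 2.03, SE 0.625, edgeR adjusted p = 0.00376) and its difference after Dcp did not (0.53, SE 0.607, edgeR adjusted p = 0.458). Without RNA sample 1 the rise after RppH was 2.11 on the log2 scale with an edgeR adjusted p of 0.0595. The 88-nt form rose by 1.43 after RppH (SE 0.625, edgeR adjusted p = 0.032), which was not called without RNA sample 1 (1.34, adjusted p = 0.196) or 3 (1.41, adjusted p = 0.0543). RppH exceeded Dcp for the 86-, 87- and 88-nt forms, by ratios of pooled rates of 4.59, 2.94 and 3.23, in 3 of 3 RNA samples (edgeR adjusted p = 0.00431, 0.0348 and 0.0324). Without RNA sample 1 the log2 differences were 2.31, 1.47 and 1.48 and did not pass (adjusted p = 0.0718, 0.236 and 0.227), and without RNA sample 3 those of the 87- and 88-nt forms were 1.29 and 1.64 and did not pass (adjusted p = 0.0653 and 0.0609).

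**Figure D2:**
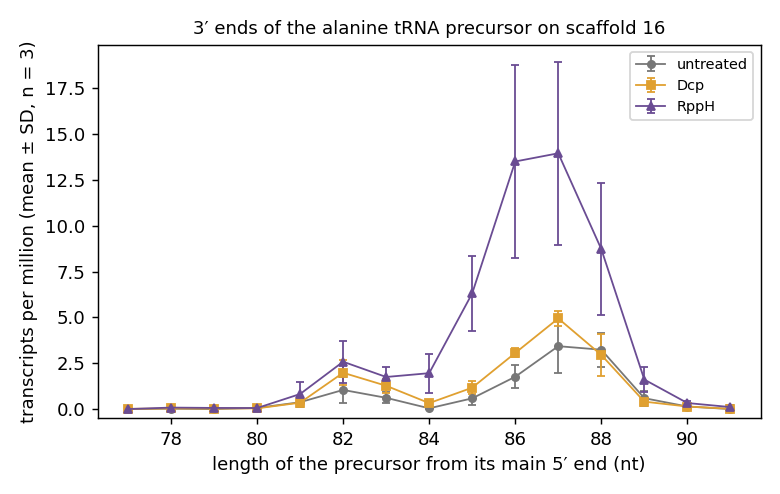
Mean abundance of transcripts of the alanine gene on scaffold 16 that start at its main 5′ end, in TPM, by length in nt and treatment; error bars are SD over 3 libraries. The 87-nt form has the highest mean in each treatment, at 3.43 TPM untreated, 4.94 TPM after Dcp and 13.9 TPM after RppH.

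The direct comparison of the enzymes placed RppH above Dcp for 22 of 34 intervals and below it for 0 (edgeR; 0 were lower at an unadjusted p under 0.05 or with DESeq2). These were 7 of 9 microRNA and 15 of 17 pre-tRNA intervals, or 8 and 15 adjusted over the list alone and 5 and 15 with the RNA sample as a block. Pre-tRNA intervals outside the alanine gene, and some microRNA intervals, passed the filter through the RppH libraries alone, which favours these shares. None of the 8 snRNA intervals differed past the threshold, and 0 did at an unadjusted p under 0.05 or with DESeq2. The dominant U1 copy had a log2 difference of 0.21 (SE 0.419, edgeR adjusted p = 0.731), and a missed threshold does not show equal levels. The U2 copy on scaffold 79 differed by −0.01 (SE 0.669, edgeR adjusted p = 0.987). In contrast, the 96-nt serine pre-tRNA of tRNA9-SerAGA on scaffold 9 (2215144 to 2215239, minus strand; chosen after its values were seen) was at 0.119 ± 0.117 TPM after Dcp and 7.13 ± 1.05 TPM after RppH (log2 difference 5.89, SE 0.993, edgeR adjusted p = 4.46e-05, higher in 3 of 3 RNA samples). ccm-MIR12463b differed by 2.16 (SE 0.713, edgeR adjusted p = 0.0108), which was 1.31 without RNA sample 3 (adjusted p = 0.123). ccm-IIM-27 differed by 2.49 (SE 0.815, edgeR adjusted p = 0.0108), and by 2.15 with the RNA sample as a block (adjusted p = 0.124) and 3.04 without RNA sample 2 (adjusted p = 0.0507). ccm-IIM-12a differed by 1.43 (SE 0.695) and did not pass (edgeR adjusted p = 0.0727), but it passed with limma and a pseudocount of 0.1 (1.67, adjusted p = 0.0126) or 10 (0.50, adjusted p = 0.0183).

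**Figure D3:**
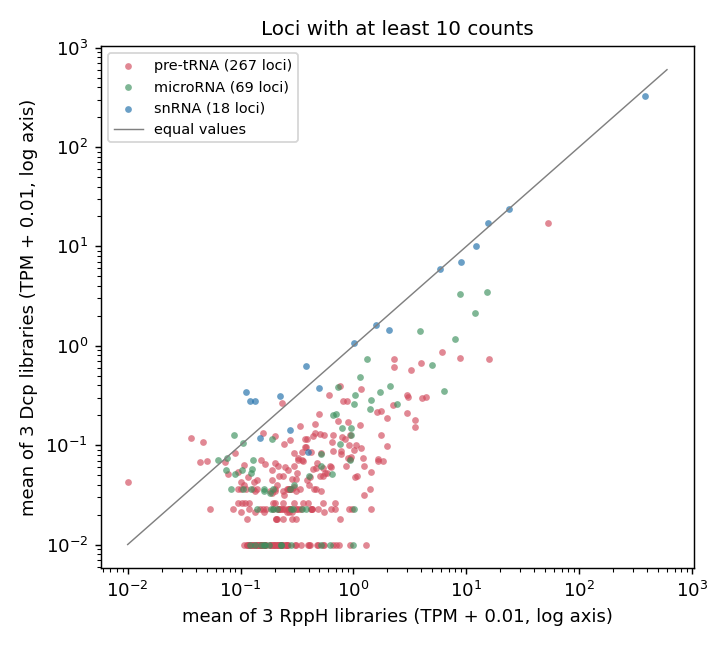
Mean of 3 Dcp libraries against mean of 3 RppH libraries (TPM + 0.01, log axes) for the 354 loci with at least 10 counts, coloured by class; the grey line marks equal values. The most abundant snRNA loci lie near the line and some of the 18 with low values do not, and most of the 267 tRNA genes and 69 microRNA loci lie to its right.

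At the level of loci, RppH was above Dcp for 39 of 69 microRNA loci, 177 of 267 tRNA genes and 0 of 18 snRNA loci (edgeR; 1 snRNA locus at an unadjusted p under 0.05, 0 with DESeq2). Adjusted over the list alone the counts were 39, 181 and 0. The total of 216 was 64 with the RNA sample as a block, with 9 microRNA loci and 55 tRNA genes, and 76 with DESeq2. It was 0 without RNA sample 1, where 165 loci had an unadjusted p under 0.05 in edgeR, and DESeq2 called 0, with 8 at an unadjusted p under 0.05. Leaving out Dcp replicate 2 or 3 gave 112 and 96, and leaving out RppH replicate 1 or 3 gave 140 and 94. Median of ratios scaling over the 34 intervals moved this comparison by 2.92 on the log2 scale and turned the split to 2 higher and 14 lower, and TMM moved it by 1.88 and gave 7 higher and 10 lower. Under median of ratios the dominant U1 copy was lower after RppH than after Dcp (log2 difference −2.79), and ccm-MIR12463b, ccm-IIM-27, ccm-IIM-12a and the 3 alanine intervals pointed the other way. Among the 354 loci, median of ratios gave 1 higher and 20 lower, and TMM gave 10 higher and 12 lower.

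Combining the comparisons, 20 intervals were higher after both enzymes: 9 microRNA, 8 snRNA and 3 pre-tRNA intervals. Of these, 7 microRNA intervals and the 3 pre-tRNA intervals were also higher after RppH than after Dcp, and 0 snRNA intervals were. A further 12 intervals, all pre-tRNA, were higher after RppH than in both untreated and Dcp RNA without passing in Dcp against untreated. The filter favoured this second set, since pre-tRNA intervals outside the alanine gene passed it through the RppH libraries alone. With the RNA sample as a block 18 intervals were higher after both enzymes (8 microRNA, 8 snRNA and 2 pre-tRNA), of which 4 microRNA and the 2 pre-tRNA intervals were also higher after RppH than after Dcp, and 14 belonged to the second set (1 microRNA and 13 pre-tRNA). With limma on log2(TPM + 1) in place of edgeR, 12 intervals were higher after both enzymes and 20 belonged to the second set. Median of ratios scaling gave 7 and 0, and TMM gave 14 and 7. Among loci, 48 were higher after both enzymes (19 microRNA, 16 snRNA and 13 pre-tRNA), and 193 belonged to the second set (28 microRNA and 165 pre-tRNA). With the RNA sample as a block these were 29 and 59, with DESeq2 38 and 69, and without RNA sample 1 they were 6 and 0. Median of ratios gave 15 and 0, and TMM gave 26 and 7.

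Relative to the other tested intervals, camera placed snRNAs above the rest in Dcp against untreated (adjusted p = 5.08e-09) and below the rest in RppH against Dcp (adjusted p = 4.55e-07). Both calls held with an estimated correlation (adjusted p = 0.0175 each). It also placed them above the rest in RppH against untreated (adjusted p = 0.000158), which was lost (adjusted p = 0.108 with an estimated correlation). Pre-tRNAs lay below the rest in Dcp against untreated (adjusted p = 4.55e-07), which held (adjusted p = 0.0175 with an estimated correlation). They lay below the rest in RppH against untreated (adjusted p = 0.000579), which was lost (adjusted p = 0.108 with an estimated correlation), and above it in RppH against Dcp (adjusted p = 0.00363), also lost (adjusted p = 0.111 with an estimated correlation). MicroRNA intervals did not stand apart (adjusted p = 0.739, 0.739 and 0.496). The 17 pre-tRNA intervals came from 9 tRNA genes, and several were forms of the alanine gene that differ in length. Each form counted as a separate member of its class, and of the rest when another class was tested. Camera was not run per gene or without the alanine gene, so how far the class calls rest on that gene was not tested.

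The changes after the 2 enzymes, taken here as differences of mean log2(TPM + 1) from the same untreated libraries, correlated across the 34 intervals (Pearson r = 0.881, Spearman rho = 0.686). The intervals are not independent replicates. For comparison, all 9 libraries, controls included, were simulated as unchanged at the untreated rates, which gave a mean r of 0.433. The observed covariance was 2.03, against a simulated 0.0108, a difference of 2.02 (100 simulations). The 20 intervals higher after both compared with 19.4 for independent lists of 33 and 20 among 34. With 33 of 34 intervals in the first list the overlap could hardly differ from this, so it says nothing about agreement. With 3 untreated libraries the controls could not be split into separate sets of at least 2 for each enzyme, so part of the excess of r over the simulated r may come from the shared controls. Most untreated rates were near 0, where log2(TPM + 1) hardly varies, so a simulated covariance near 0 was set in advance. With such low controls the observed changes mostly follow the abundance after each enzyme. The r and the covariance difference therefore do not show agreement beyond a shared ranking of abundance.

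The RppH to Dcp ratio of each class differed among RNA samples. For microRNA totals the ratio ran from 2.71 to 19.0 over the 3 RNA samples, for pre-tRNA totals from 5.21 to 10.2, and for snRNA totals from 0.784 to 1.79. RNA sample 3 had the highest ratio in each class, and without it the microRNA ratio of means was 2.80 instead of 4.92. The ratio of means was 6.57 for pre-tRNA and 1.13 for snRNA (exact two-sided permutation p = 0.1 for pre-tRNA and microRNA, 0.7 for snRNA). On the log2 scale the pre-tRNA ratio exceeded the snRNA ratio by 2.57 ± 0.14 (SD, n = 3 pairs), and the microRNA ratio exceeded it by 2.27 ± 1.01. Both were higher in 3 of 3 RNA samples (exact two-sided sign-flip permutation p = 0.25, the smallest that 3 pairs allow). The pre-tRNA ratio exceeded the microRNA ratio in 2 of 3 RNA samples, by 0.30 ± 1.04 (exact permutation p = 0.75), which was within the spread. Without the alanine gene it did so in 3 of 3 RNA samples, by 0.95 ± 0.71 (exact permutation p = 0.25, the smallest possible).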

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

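The locus level, TMM, DESeq2, limma on log2(TPM + 1), the class totals without single genes and all tests of other splits were chosen after the data were seen. Over the 34 intervals, the counts for RppH against untreated, Dcp against untreated, RppH against Dcp, both enzymes, and RppH above Dcp but not past in Dcp were 33, 20, 22, 20 and 12. DESeq2, library totals without the 10 highest features and the RNA sample as a block stayed within 1.5 times, as did the first 3 counts in fits of 2 groups, with block counts of 34, 18, 20, 18 and 14. Without an RNA sample or a library the ranges were 30 to 34, 14 to 22, 16 to 22, 14 to 22 and 8 to 18. With limma on log2(TPM + 1), with or without a trend, Dcp against untreated, both enzymes and the last count were 12, 12 and 20, and with a pseudocount of 10 they were 8, 8 and 23. Without a filter the 5 counts were 220, 34, 80, 33 and 72, and with a TPM of at least 10 they were 4, 4, 0, 4 and 0 among 4 intervals, where edgeR at an unadjusted p under 0.05 and DESeq2 also gave 0 for RppH against Dcp. The 4 were all snRNA, a class without calls in RppH against Dcp over the 34 intervals, and without a filter 2469 intervals were tested.

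Median of ratios scaling gave 14 calls for RppH against untreated, 7 for both enzymes and 0 for the last count, and TMM gave 7 for the last. By construction both take the tested intervals as their reference, and median of ratios sets the middle of them near no change. Under median of ratios the 87-nt, 86-nt and 88-nt alanine pre-tRNA forms had log2 values of −4.28, −3.51 and −4.89 for RppH against untreated and −1.57, −0.87 and −1.48 for RppH against Dcp. ccm-MIR12463b had −0.18 and −0.67. For RppH against Dcp, ccm-IIM-27 and ccm-IIM-12a had −0.39 and −1.36, the U1 copies on scaffold 1 (2523679), scaffold 29 and scaffold 1 (2337806) −2.79, −2.66 and −2.69, and the U4 copy on scaffold 12 −2.40. For Dcp against untreated the 87-nt and 86-nt alanine forms had −2.72 and −2.64. All of these changed sign from the edgeR fit on library totals.

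Uncalled log2 differences near 0 in RppH against Dcp changed sign when an RNA sample was left out: −0.26 to 0.064 and −0.41 to 0.24 for the U2 copies on scaffolds 29 and 79, −0.17 to 0.42, −0.11 to 0.53 and −0.017 to 0.55 for the 3 U1 copies in the order above, and −0.14 to 0.070 for the U4 copy on scaffold 99. The microRNA class, which camera did not call, changed direction in RppH and Dcp against untreated with the block (adjusted p = 0.664 and 0.913), with limma and a pseudocount of 10 (0.387 and 0.442) and without RNA sample 2 (0.152 to 0.785 and 0.219 to 0.879 over the 3 RNA samples left out).

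At the locus level the counts were 323, 48, 216, 48 and 193. With the RNA sample as a block they were 203, 30, 64, 29 and 59, and the block changed 1 call of a named feature (ccm-IIM-27, RppH against Dcp). Limma gave 10 for Dcp and 9 for both enzymes, and DESeq2 gave 76 for RppH against Dcp and 69 for the last count. TMM gave 74, 22, 26 and 7 for RppH against untreated, RppH against Dcp, both enzymes and the last, and median of ratios gave 25, 31, 21, 15 and 0. A minimum of 30 counts gave 174, 129 and 104 for RppH against untreated, RppH against Dcp and the last, with fewer loci tested. Without an RNA sample or a library the ranges were 196 to 323, 6 to 58, 0 to 197, 6 to 58 and 0 to 204, where the 0 came without RNA sample 1 and with 2 libraries per group. For the last count, leaving out Dcp replicate 2 or 3 gave 107 and 85, and leaving out RppH replicate 1 or 3 gave 127 and 87. Without RNA samples 2 and 3 it was 116 and 53, and RppH against Dcp was 124 and 57. The cause was not tested.

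An estimated correlation left 3 of 6 class calls. The correlation of the enzymes' changes was 0.812 with a pseudocount of 0.1, 0.954 with 10, and 0.856 to 0.902 without an RNA sample. Without the alanine gene the pre-tRNA total was 27.0-fold (RppH over untreated), 2.77-fold (Dcp over untreated) and 9.75-fold (RppH over Dcp), against 12.4, 1.88 and 6.57 with it. Class totals without an RNA sample ran from 62.4 to 113, 13.0 to 22.3 and 2.80 to 7.19 for microRNA, and from 594 to 949, 480 to 762 and 0.878 to 1.31 for snRNA. For pre-tRNA they ran from 11.8 to 13.2, 1.69 to 2.25 and 5.25 to 7.52. Of 345 settings of named features and classes, 284 kept direction and side of the threshold, 25 lost a call, 6 gained one and 30 changed direction.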

Other observations

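The tests of counting error, of length among loci of lengths both classes have, of microRNA caps, of single libraries for the alanine gene, of pre-tRNA ends and of other splits were chosen only after the results were seen. After RppH, alanine precursors with the anticodon TGC made up 22.7% of the pre-tRNA signal (53.3 ± 19.3 TPM, SD, n = 3, from 8 genes), followed by serine AGA (20.6 ± 3.66 TPM, 10 genes), aspartate GTC (19.2 ± 5.33 TPM, 23 genes) and asparagine GTT (12.3 ± 1.93 TPM, 16 genes). Single genes held most of the first 2: tRNA14-AlaTGC on scaffold 16 had 4694 of 4732 alanine counts, and tRNA9-SerAGA on scaffold 9 had 1394 of 1795 serine counts. Pre-tRNAs had sharper 5′ than 3′ ends. Among 166 tRNA genes with at least 20 RppH counts, the commonest 5′ end held a median of 97.3% of counts and the commonest 3′ end 45.2%. The 5′ end was the narrower in 156 genes and the 3′ end in 8 (exact binomial p = 9.8e-37 across genes, which are not independent replicates).

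Detection of microRNA loci differed between treatments. Of 126 listed loci, 19 had a count in any untreated library, 80 in any Dcp library and 118 in any RppH library. The 10 most counted loci held 70.5% of microRNA counts. One U1 copy held 82.4% ± 1.60 of snRNA counts after Dcp and 83.6% ± 1.06 after RppH (SD, n = 3 each). Loci named MIR and loci named IIM differed by 0.12 in mean log2(TPM + 0.1) after RppH (54 and 72 loci, SE 0.294, permutation p = 0.68) and by −0.25 in mean log2 Dcp to RppH ratio (15 and 14 loci, SE 0.613, permutation p = 0.69), so neither difference was detectable.

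MicroRNA loci had a higher Dcp to RppH ratio than pre-tRNAs in RNA samples 1 and 2 (odds ratios 1.95 and 1.78) but a lower one over all loci in RNA sample 3 (0.537, 95% counting interval 0.458 to 0.627), while with untreated levels subtracted the ratio was higher for microRNA in each sample (0.356, 0.334 and 0.0446, against 0.108, 0.126 and 0.0242). A monophosphate background is argued against as the source. Untreated levels made up more of the Dcp total for pre-tRNA (19.0 of 35.8 TPM) than for microRNA (1.13 of 18.8 TPM). They thus work against the pattern. Loci with 0 untreated counts had odds ratios of 2.64, 3.09 and 1.75 (smallest lower bound 1.3). That bound covers counting error only, which replicates exceeded, and 0 counts do not show that a locus had no background. Transcript length cannot be told apart: among loci of 106 to 145 nt, lengths both classes have, the odds ratios were 3.92, 4.79 and 1.89 (smallest lower bound 1.08), but median lengths still differed there (137 and 107 nt, 61 microRNA loci and 13 tRNA genes). A few loci cannot be told apart either, since without the 5 most counted of each class the odds ratios were 2.43, 2.26 and 1.24, with a lower bound of 0.989 in RNA sample 3. A mixture of capped and triphosphate ends may underlie an intermediate ratio, and so may a lesser action of Dcp on triphosphates, which was not tested.

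Among 29 microRNA loci with at least 50 counts the pooled ratio ran from 0 at ccm-IIM-98 (55 RppH counts) and ccm-MIR12487b (86 RppH counts) to 0.494 at ccm-IIM-63b. Whether loci differ beyond noise cannot be told apart. Counts varied between loci by more than counting error for microRNA (chi-square divided by its degrees of freedom 8.19, 5.62 and 7.25) and for snRNA alike (6.37, 4.78 and 9.06), and replicates of 1 treatment did so too. Between RNA samples 1 and 2 the microRNA ratios gave a Spearman rho of 0.34 over 20 loci (permutation p = 0.14, adjusted 0.224) and a Pearson r of 0.267 (permutation p = 0.26, adjusted 0.416), while samples 1 and 3 gave a rho of 0.604 (24 loci, permutation p = 0.0019, adjusted 0.00507) and samples 2 and 3 one of 0.203 (22 loci, permutation p = 0.36, adjusted 0.48), among 8 such relations across loci, which are not independent replicates. Transcript length remains open, with a rho of 0.15 over 29 loci (permutation p = 0.44). Caps on part of the microRNA transcripts also remain open: 2 of 29 loci, ccm-MIR12490a and ccm-IIM-39, had intervals that reached the snRNA ratio in RNA samples 1 and 2, against 1 of 78 tRNA genes and 8 of 11 snRNA loci (Fisher's exact p = 0.178, microRNA against tRNA genes), and 12 of the 29 had intervals whose lower bounds reached down to the pre-tRNA ratio in these samples. In RNA sample 3 the ratios of these 2 loci were far lower, at 0.0515 and 0.0539. Both lie on the minus strand of scaffold 59, near ccm-MIR12490b (pooled ratio 0.483), which fell just short of the snRNA ratio in RNA sample 2. Whether these loci are related copies was not examined, so they may not be independent. An interval reaches the snRNA ratio when its upper counting bound does, so loci with few counts pass more easily. The dominant U1 copy did not reach it, nor did ccm-IIM-12a (312 Dcp and 783 RppH counts, ratios 0.749 and 0.554 in RNA samples 1 and 2). The shares of loci and the Fisher's exact test thus partly reflect interval width and do not decide on caps.

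The alanine gene tRNA14-AlaTGC held 63.7% ± 5.08 of untreated pre-tRNA counts (SD, n = 3) and 22.1% ± 2.72 of those after RppH. This was not the work of a single library, since the lowest untreated share was 58.3% (95% Wilson interval 54.3 to 62.1%). Whether untreated and RppH libraries held the same set of 3′ ends was not decided by mean length. Mean length differed in no one direction (−0.165, 0.229 and 0.266 nt, untreated minus RppH), and changes within the range of lengths can cancel in a mean. Transcripts of 84 to 86 nt, lengths picked after the profile was seen, were 11.8%, 27.6% and 22.7% of the gene's counts untreated. After RppH they were 37.2%, 45.6% and 44.1%. The odds ratios were 4.41, 2.20 and 2.69 (smallest lower 95% bound 1.67), which argues against equal shares of the 3′ ends in these counts. The bounds cover counting error only. No biological explanation was tested, and near-identical copies were not examined.

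Other splits of the libraries were counted for each result. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05; only 1 of the 10, the real one, was as large in each contrast. The real counts of 33, 20 and 22 intervals compared with a highest other of 0, 1 and 0 (and 0 in each among the 4 splits that part all pairs), and those of 323, 48 and 216 loci with 0. Of 100 regroupings of all 9 libraries, 2 gave as many intervals higher after both enzymes (20, highest other 20), and of 100 that kept 1 library of each RNA sample in each group, 4 did (highest other 21). A regrouping and the one with Dcp and RppH exchanged throughout give the same value here and were counted once; a first draw that counted them apart gave 5 of 100. The others as large kept the untreated libraries and exchanged Dcp with RppH in some RNA samples, and regroupings that moved an untreated library gave at most 1 and 0. By the first counting the share was not under 0.05, so chance was not firmly excluded for this count. The values show only that no regrouping that moved an untreated library came near it, and the count does not test which enzyme a library had. With the RNA sample as a block, 1 of 100 gave as many (18, highest other 12), so chance was excluded for the blocked count. For intervals higher after RppH and above Dcp, 1 of 100 gave as many in either set (12, highest other 3 and 1), so chance was excluded. For loci, 1 of 100 gave as many in either set for both enzymes (48, highest other 16 and 36) and for RppH above Dcp (193, highest other 159 and 156). Regroupings thus came close to the 193, and with the RNA sample as a block 59 loci compared with a highest other of 0, so chance was excluded for the blocked count, while the count was 0 without RNA sample 1. For the number of class calls, 18 and 28 of 100 gave as many in the 2 sets (6, highest other 7 in each), so chance could not be excluded.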
